A study of Homo sapiens and Mus musculus with 24 samples.

How the data were processed

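RNA sequencing libraries of SOAT1 knockout and vector control cells were compared in 4 experiments of 6 libraries each: cultured Hepa1-6, cultured Huh7, Huh7 tumours of hosts given PBS and Huh7 tumours of hosts given T cells. Groups were taken from the sample titles, 3 libraries to a group. The library kit is given differently in the series text and in the labels, so strand use was not settled. Reads were aligned with HISAT2, per the submitters' processing notes; its version, the genome builds and the read counter are not given in the sources used here.

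The deposited tables of the tumours hold counts and FPKM of each library, with a log2 fold change, a p-value and an adjusted p-value for each gene, per the file headers. The deposited tables of the cultured cells hold FPKM of each library, the normalized mean signal of each group, a log2 fold change, a p-value and a q-value made by the authors with DESeq2, per the file headers. In the Hepa1-6 table the FPKM columns are headed only as expression and were taken as FPKM, as their values allow. The tables list 16277 genes for Hepa1-6, 18103 for cultured Huh7, 13659 for PBS tumours and 13825 for T cell tumours. No other column per sample was left unused (0 columns).

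For the cultured cells, whole reads were rebuilt from the FPKM and the group means. In all libraries 100% of the values above 0 lay within 0.05 of a whole number. Library totals were 34.1, 31.8 and 36.5 M for Huh7 vector, 36.4, 33.9 and 38.8 M for Huh7 knockout, 38.5, 37.7 and 37.6 M for Hepa1-6 vector, and 38.4, 37.6 and 38 M for Hepa1-6 knockout. At these totals 3 reads are 0.077 to 0.094 CPM, against 0.026 to 0.1 CPM in PBS tumours and 0.104, 0.391 and 0.138 CPM in the knockout T cell tumours. Replicates of a group differed by more than counting noise in every pair, with a chi-square per degree of freedom of 2.9 or more. The 10 most abundant genes held 5.5 to 11.0% of the reads of a library. Features without a gene name, 713 in the PBS and 706 in the T cell tumours with 0.637 to 0.726% of counts, were kept in the library totals given in the text. They were left out of the main tests, including the library sizes and CPM of those tests.

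The tests, samples, thresholds, alternatives, 31 gene lists and the rule for naming genes were fixed before the data were examined. Tumour counts were tested with the edgeR quasi-likelihood F test after TMM scaling and filtering by expression. Cultured cells, planned for the same test if counts were present, were tested as planned for tables with FPKM alone: limma with a trend on log2(FPKM + 1), for genes with at least 1 FPKM in 3 or more libraries. No further scaling was applied to the FPKM. Count tests on rebuilt reads, fits that keep unnamed features and the whole comparison of culture with PBS tumours on rebuilt reads were added later. P-values were adjusted by Benjamini-Hochberg within a comparison, with a threshold of 0.05. Contrasts across treatments used 1 fit of the 12 tumours over the 12877 named genes shared by both tables, of which 95.1% have lengths within 10% of each other, and the comparison of culture with PBS tumours used 12623 shared genes. Samples of culture and tumour tables were normalized apart by the authors, and no value was compared between them except as a knockout effect, apart from the ratio of marker levels in the closing section.

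Gene lists with 3 or more tested members were tested with camera at a preset correlation of 0.01, then with an estimated correlation, and with fry. Named genes are SOAT1 in every library, the 6 largest rises and 6 largest falls past the threshold with a mean of at least 5 (CPM or FPKM) in the higher group and no overlap between groups, and up to 4 members past the threshold of up to 5 lists with the smallest camera p. A list was eligible with a camera adjusted p under 0.05 or with 3 members past the threshold. For an eligible list with no member past the threshold, up to 4 members with the smallest p are named. Overlap between experiments was tested with Fisher's exact test, with mouse and human genes matched by symbol.

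Tests were tried on simulated data with the spread of these libraries, 50 genes changed by each of 4 folds and 200 in all. At 2-fold, 100% of changed genes were called in Hepa1-6, 96% in cultured Huh7, 80% in PBS tumours, 70% in T cell tumours, 74% and 78% between treatments in vector and knockout tumours, 38% for the interaction with T cells and 60% for the interaction with growth. At 1.5-fold these were 80%, 92%, 34%, 20%, 42%, 32%, 6% and 22%. These shares hold for 200 changed genes. With fewer changed genes the Benjamini-Hochberg cutoff is stricter and the shares are lower. Of the calls up to 8.2% were false, and 0 of 30 unchanged lists were called in each comparison. The simulated genes were drawn independently of each other. The list result therefore says nothing of false list calls where genes are correlated.

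Replicate numbers are shared by the groups, and whether they pair the libraries was checked by the correlation of deviations from the group means. In T cell tumours each same-numbered pair had a correlation of 0.12 to 0.16, over the limit of 0.1, so these libraries were taken as paired by number from the data and the blocked result is printed beside the other. No label gives a pairing. Pairs of different number had -0.12 to -0.04 in T cell tumours. They reached 0.14 in cultured Huh7 and 0.46 between vector PBS and T cell tumours, so 0.12 to 0.16 does not establish a pairing. Alternatives were other size factors, DESeq2, other filters, a replicate block, pseudocounts of 0.1 and 0.01, a fit of all 12 tumours and leaving out each library in turn. Low-count filters removed no gene listed for the tumours, so those alternatives tested nothing there. Software was R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.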

Results

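RNA was sequenced from 24 libraries in 8 groups of 3. Cultured cells came from Hepa1-6, a mouse hepatoma line, and Huh7, a human hepatocellular carcinoma line, each carrying an empty vector or a SOAT1 knockout. Tumours of Huh7 cells, whose titles name the NSG strain of immunodeficient mice, came from hosts given PBS or T cells through the tail vein, again with vector and knockout cells. SOAT1 is the sterol O-acyltransferase of the endoplasmic reticulum, which esterifies free cholesterol for storage in lipid droplets. The titles call the edited groups knockout, whereas the genotype field calls them knockdown; the word of the titles is used here. The labels call the injected cells T cells, while the name of their table reads as CAR-T cells. Whether they carried a chimeric antigen receptor is not stated, and the word of the labels is used. By its title, the series asks whether losing the enzyme makes liver cancer cells easier for T cells to act on. The labels do not say that the 3 replicates of a group were separate cultures or animals, so p-values measure only the spread between these samples.

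Total reads per library, with M for mega, ranged from 37.6 to 38.5 M in Hepa1-6 and from 31.8 to 38.8 M in cultured Huh7, as rebuilt from the deposited values. The PBS tumours held 29.9, 114.2 and 66.9 M counts with vector and 36.7, 43.2 and 30 M with knockout. The T cell tumours held 44.1, 29.5 and 22.1 M counts with vector and 28.8, 7.7 and 21.7 M with knockout, so that knockout replicate 2 was the shallowest of all libraries. Values with ± are mean and SD of 3 libraries, in FPKM for cultured cells and in counts per M reads (CPM) for tumours. Fold changes of cultured cells are on the log2(FPKM + 1) scale, which understates the change of genes with low values.

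SOAT1 transcript was lower in the knockout group of all 4 experiments. It fell from 17 ± 1.15 to 5.19 ± 0.441 FPKM in cultured Huh7 (log2 fold change -1.54, SE 0.07, limma adjusted p = 2.32e-07). In PBS tumours the fall was from 83.5 ± 3.01 to 29.1 ± 4.91 CPM (-1.52, SE 0.13, edgeR adjusted p = 0.012). In T cell tumours it fell from 97.9 ± 5.78 to 39.8 ± 6.14 CPM (-1.31, SE 0.14, edgeR adjusted p = 0.0159). Soat1 in Hepa1-6 was near the lower limit of expression, at 1.43 ± 0.327 FPKM with vector and 0.594 ± 0.168 with knockout (-0.61, SE 0.12, limma adjusted p = 0.0154). On rebuilt reads edgeR gave -1.29 (adjusted p = 0.00129). In each experiment every knockout library lay below every vector library, although transcript remained in all of them. The call was lost in Hepa1-6 without knockout replicate 1 (limma adjusted p = 0.0683), and with any 1 vector replicate left out the gene fell under the expression filter. It was lost in PBS tumours with the replicate number as a block (edgeR adjusted p = 0.146). In PBS tumours it was also lost without vector replicate 2 (0.0895), vector replicate 3 (0.0519), knockout replicate 1 (0.0864) or knockout replicate 2 (0.213). The fold changes of these PBS fits stayed between -1.55 and -1.44. In T cell tumours it was lost without vector replicate 1 (0.0836), knockout replicate 1 (0.108) or knockout replicate 3 (0.0851), with fold changes of -1.35, -1.20 and -1.32.

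**Figure D1:**
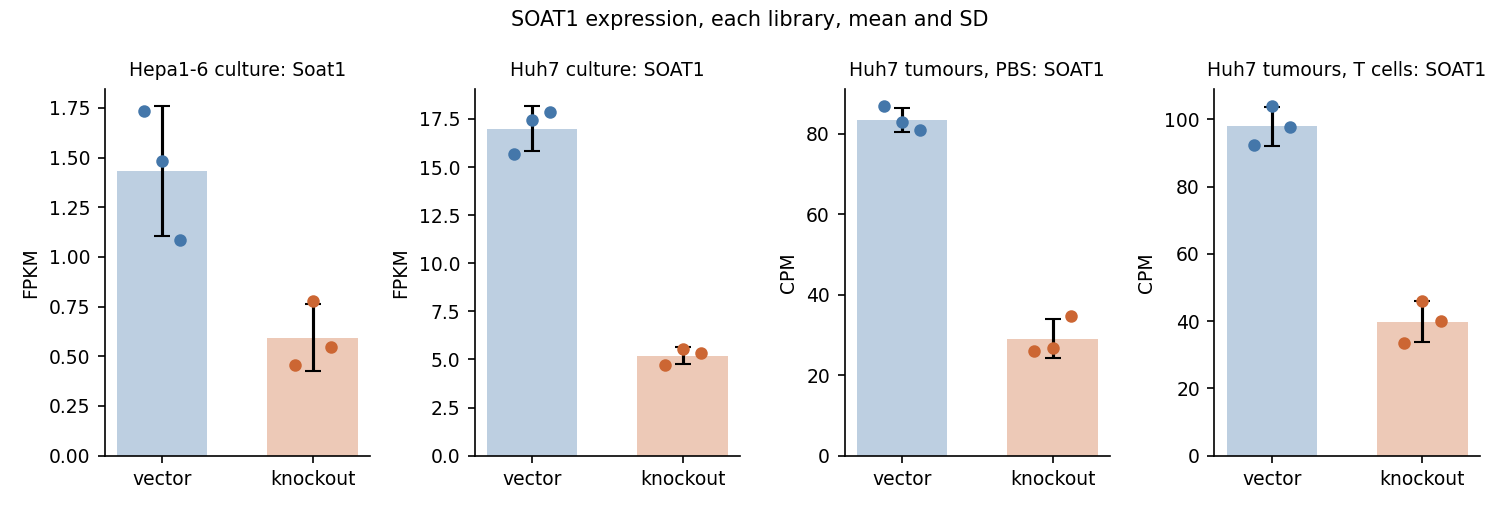
SOAT1 expression in each library of the 4 experiments, as FPKM for cultured cells and CPM for tumours; bars are means, error bars the SD and points the 3 libraries of a group. Mean levels are 1.43 and 0.594 FPKM in Hepa1-6, 17 and 5.19 FPKM in cultured Huh7, 83.5 and 29.1 CPM in PBS tumours and 97.9 and 39.8 CPM in T cell tumours, for vector and knockout.

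In cultured Hepa1-6 cells, the comparison asked which transcripts differ with loss of the enzyme. Ccl2, a chemokine that attracts monocytes, fell from 54.5 ± 0.301 to 13.1 ± 2.77 FPKM (log2 fold change -1.99, SE 0.11, limma adjusted p = 9.59e-05). Tff1, a secreted trefoil peptide, fell from 386 ± 6.53 to 183 ± 11.5 FPKM (-1.07, SE 0.05, limma adjusted p = 2.79e-05). Of the genes of cholesterol synthesis and uptake 14 of 25 fell and the other 11 did not pass, and 6 of the 25 had positive fold changes (camera adjusted p = 2.08e-08; adjusted p = 0.659 with an estimated correlation). Of the hepatocyte proteins 6 of 11 rose and 1 fell (camera adjusted p = 0.000134; adjusted p = 0.659 with an estimated correlation). Alpha-fetoprotein (Afp) rose from 890 ± 48.8 to 1270 ± 23.4 FPKM. Nkd1 and Notum, feedback inhibitors of Wnt signalling, rose from 26.8 ± 3.35 to 59.0 ± 8.15 FPKM and from 4.28 ± 1.36 to 9.61 ± 1.07 FPKM.

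The other large rises in Hepa1-6 were in ND6, a mitochondrial subunit of complex I (23.6 ± 3.32 to 74.6 ± 25.7 FPKM), and Tgfbi, an extracellular matrix protein (35.8 ± 6.01 to 83.2 ± 8.88). Others were in Ppp1r3c, which targets a phosphatase to glycogen (2.03 ± 0.35 to 5.49 ± 0.429), and Gpc3, an oncofetal proteoglycan (33.9 ± 5.74 to 67.0 ± 5.35). The other large falls were in Sprr1b (19.5 ± 1.89 to 8.63 ± 1.12 FPKM) and Edn1, the endothelin precursor (5.1 ± 0.344 to 1.96 ± 0.129). Serpinb9b (18.6 ± 1.11 to 9.71 ± 1.55) and the matricellular gene Ccn1 (87.1 ± 44.5 to 37.5 ± 3.5) fell as well. ND6 overlaps transcripts of the opposite strand and Serpinb9b has close paralogs, so that their reads are hard to tell apart. Of the cholesterol genes, Hmgcs1 fell from 55.2 ± 5.43 to 30.7 ± 1.3 FPKM and Hsd17b7 from 5.21 ± 0.605 to 2.55 ± 0.0742. LXR targets and genes of cholesterol efflux rose in 4 of 7 cases: Apoe from 166 ± 6.36 to 242 ± 15.2 FPKM and Abca1 from 16.4 ± 1.37 to 25.7 ± 3.7. Abcg1 rose from 4.96 ± 0.459 to 6.89 ± 0.415, and Mylip, a ubiquitin ligase gene, from 2.99 ± 0.456 to 4.55 ± 0.75. Among the hepatocyte proteins, Fgb (141 ± 17.5 to 248 ± 10.1 FPKM), Itih2 (81.2 ± 6.47 to 119 ± 6.63) and Hpx (17 ± 0.824 to 27.4 ± 1.08) rose, while Apob fell by 0.42. NF-kB targets and chemokines held 5 lower members of 15, including Cxcl1 (60.3 ± 3.6 to 36.8 ± 4.36 FPKM) and the feedback inhibitors Tnfaip3 and Tnip1. The immediate early genes held 2 lower of 11, Atf3 and Jund.

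In all, 1329 of 10206 genes passed in Hepa1-6, 764 higher and 565 lower, and 13 of them changed at least 2-fold. By camera with a preset correlation, 6 of the 23 lists tested passed: cholesterol synthesis (adjusted p = 2.08e-08), hepatocyte proteins (0.000134), NF-kB targets (0.000187), immediate early genes (0.0023), LXR targets (0.00348) and hepatocyte transcription factors (0.0305; 6 of 12 higher). With an estimated correlation none passed (adjusted p = 0.247 for NF-kB targets and adjusted p = 0.659 for each of the others). Members past the threshold when adjusted over the list alone numbered 17 lower and 1 higher for cholesterol synthesis and 9 higher and 1 lower for hepatocyte proteins. They numbered 6 lower for NF-kB targets, 2 lower for immediate early genes, 4 higher for LXR targets and 6 higher for the transcription factors. On rebuilt reads, with another test, scaling and filter and 13047 genes tested, edgeR called 1658 genes, 784 higher and 874 lower. The count was 712 with no filter on low values, 572 without vector replicate 1, 572 without vector replicate 2, 2027 without vector replicate 3, 409 without knockout replicate 1 and 357 without knockout replicate 2.

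In cultured Huh7 cells the same question gave a far longer list. VIM, the intermediate filament vimentin of mesenchymal cells, fell from 106 ± 0.806 to 21.7 ± 1.11 FPKM (log2 fold change -2.24, SE 0.04, limma adjusted p = 1.86e-09), and the peptidase gene DPP4 fell from 60.9 ± 1.98 to 21.9 ± 0.497 FPKM. HP, the haemoglobin-binding plasma protein haptoglobin, rose from 16.9 ± 0.971 to 73.8 ± 3.1 FPKM (2.07, SE 0.05, limma adjusted p = 6.19e-09). FGB, the fibrinogen beta chain, rose from 213 ± 2.04 to 501 ± 3.75 FPKM (1.23, SE 0.02, limma adjusted p = 1.86e-09). Of the genes of cholesterol synthesis and uptake 23 of 25 fell (camera adjusted p = 6.25e-10; adjusted p = 0.184 with an estimated correlation), and of the mesenchymal genes 11 of 12 (0.000205; adjusted p = 0.184 with an estimated correlation). The hypoxia and glycolysis list held 11 higher and 2 lower genes of 18, and the list of NRF2 targets and ferroptosis 12 higher and 2 lower of 17. Both had a camera adjusted p = 0.000205 and adjusted p = 0.2 with an estimated correlation.

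The remaining large rises in cultured Huh7 were in the acute-phase genes SAA1 (3.0 ± 0.757 to 14.3 ± 1.34 FPKM) and LCN2 (5.12 ± 0.496 to 22.4 ± 1.41). They also included the glucose transporter gene SLC2A2 (1.42 ± 0.0722 to 7.07 ± 0.274) and SERPINA7, which encodes a carrier of thyroid hormone (1.28 ± 0.0151 to 6.51 ± 0.52). SAA1 and HP have near-identical paralogs, whose reads are hard to tell apart. The remaining large falls were in TP53INP1, a target of p53 (11.1 ± 0.298 to 3.24 ± 0.21 FPKM), COL9A3 (6.54 ± 0.516 to 1.73 ± 0.223) and KLHL24 (7.72 ± 0.695 to 2.18 ± 0.116). HMGCS1 fell from 251 ± 9.4 to 110 ± 1.81 FPKM, FDFT1, which makes squalene, from 83.9 ± 1.85 to 41.0 ± 0.956, and MVD from 71.6 ± 0.425 to 36.2 ± 0.865. INSIG1, the sterol-responsive brake on SREBP, fell from 63.7 ± 2.88 to 27.7 ± 0.25. Among mesenchymal genes MMP14 fell from 27.0 ± 1.39 to 14.0 ± 0.405 FPKM, TGFB1 from 13.8 ± 0.441 to 8.0 ± 0.114 and ITGA5 from 21.5 ± 0.981 to 15.2 ± 0.493. Rising NRF2 targets and ferroptosis genes included FTL, the ferritin light chain (3790 ± 78.9 to 4820 ± 58.9 FPKM), and GCLM, of glutathione synthesis (log2 fold change 0.69). SRXN1 (28.1 ± 1.11 to 39.3 ± 1.8) and AIFM2 (7.99 ± 0.186 to 11.6 ± 0.535) rose with them. In glycolysis PFKFB3 rose from 12.9 ± 0.0992 to 24.8 ± 0.523 FPKM and LDHA from 310 ± 6.01 to 476 ± 3.82. ENO1 rose from 280 ± 5.09 to 407 ± 5.81 and HK2 from 13.7 ± 0.605 to 21.6 ± 0.12. Hepatocyte proteins went both ways, 12 of 19 higher and 6 lower: FGG and FGA rose by 0.83 and 0.71, whereas transthyretin (TTR) and albumin (ALB) fell by 0.79 and 0.15.

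Of 11278 genes tested in cultured Huh7, 6322 passed, 2304 higher and 4018 lower, and 73 changed at least 2-fold. By camera, 9 of 24 lists passed: cholesterol synthesis (adjusted p = 6.25e-10; adjusted p = 0.184 with an estimated correlation), mesenchymal genes (0.000205; 0.184), NRF2 targets (0.000205; 0.2), hypoxia and glycolysis (0.000205; 0.2) and hepatocyte proteins (0.00149; 0.302), the last value in each bracket being the adjusted p with an estimated correlation. The others were fatty acid synthesis (adjusted p = 0.016; adjusted p = 0.213 with an estimated correlation), fibroblast and matrix genes (0.0182; 0.2), p53 targets (0.0299; 0.2) and proliferation (0.0311; 0.232). Of fatty acid synthesis genes 11 of 14 were lower and 1 higher, and of matrix genes 6 of 7 lower. Of p53 targets 10 of 17 were lower and 1 higher, and of proliferation genes 12 of 26 were higher and 3 lower, with a median of 0.06. Adjusted over the list alone, 12 fatty acid synthesis genes and 13 p53 targets were lower, and the counts of the other 7 lists did not change. On rebuilt reads edgeR called 7615 genes, 3842 higher and 3773 lower, with 5163 of the 6322 among them. DESeq2 called 7130, 3776 higher and 3354 lower. These settings change the unit, the scaling of libraries, the test and the filter at once, with 14849 genes tested in edgeR and 18103 in DESeq2. The limma fit added no scaling to the FPKM, and the median log2 fold change over all its genes was -0.056. Small falls and the excess of lower genes in that fit are not free of this offset.

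**Figure D2:**
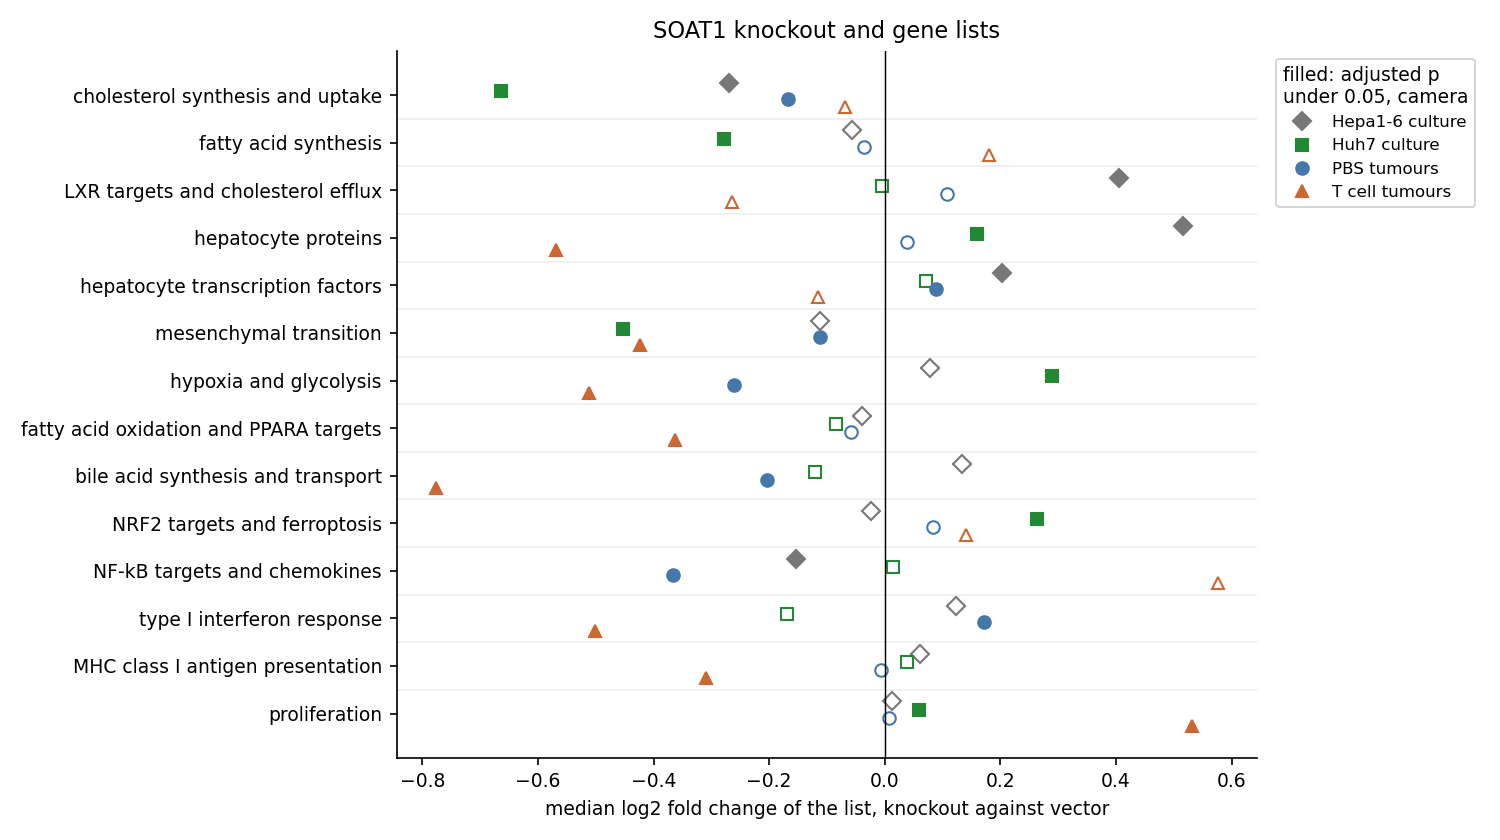
Median log2 fold change, knockout against vector, of 14 gene lists in the 4 experiments (horizontal axis); filled symbols have a camera adjusted p under 0.05 with a preset correlation, and none has one with an estimated correlation. Cholesterol synthesis lies at -0.27 in Hepa1-6, -0.66 in cultured Huh7, -0.17 in PBS tumours and -0.07 in T cell tumours, where it did not pass (camera adjusted p = 0.377), and the hepatocyte proteins lie at 0.52 in Hepa1-6 and -0.57 in T cell tumours.

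In the tumours of hosts given PBS in place of T cells, SOAT1 itself was the 1 gene of 12946 past the threshold. S100A4, a calcium-binding protein of motile cells, stood at 15.0 ± 1.74 CPM with vector and 5.75 ± 0.908 with knockout (log2 fold change -1.39, SE 0.17, edgeR adjusted p = 0.129). VIM stood at 13.6 ± 7.97 and 5.75 ± 3.38 CPM (-1.23, SE 0.54, edgeR adjusted p = 0.925). HMGCS1 stood at 1390 ± 25 CPM with vector and 1080 ± 190 with knockout (-0.35, edgeR adjusted p = 0.913), and the adhesion gene ICAM1 stood at 203 ± 10.1 and 134 ± 27.3 CPM (-0.60, edgeR adjusted p = 0.51). BAAT, which conjugates bile acids, stood at 15.2 ± 2.72 and 6.1 ± 2.14 CPM (-1.31, edgeR adjusted p = 0.354). As a set, cholesterol synthesis genes ranked lower than other genes, with 21 of 25 fold changes negative and a median of -0.17 (camera adjusted p = 6.55e-05; adjusted p = 0.499 with an estimated correlation).

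Another 8 of the 25 lists tested in PBS tumours passed camera without a member past the threshold. Lower sets were hypoxia and glycolysis (median -0.26, adjusted p = 0.000207), NF-kB targets (-0.37, 0.00401), and bile acid genes (-0.20, 0.00464), each at adjusted p = 0.499 with an estimated correlation. Mesenchymal genes (-0.11, 0.00464), the ER stress list (-0.10, 0.0354) and immediate early genes (-0.18, 0.0429) were lower sets too, also at adjusted p = 0.499 with an estimated correlation. Higher sets were hepatocyte transcription factors (0.09, 0.0265) and type I interferon genes (0.17, 0.0429). With an estimated correlation they had adjusted p = 0.499 and adjusted p = 0.633, and the interferon call was lost with the replicate block (0.078). Adjusted over the list alone, 1 NF-kB target, 1 bile acid gene and 1 mesenchymal gene were lower. At an unadjusted p under 0.05 edgeR held 682 genes. At an adjusted p under 0.05 DESeq2 called 61 (5 higher, 56 lower), and the authors' deposited table holds 64 (8 higher, 56 lower). The edgeR count was 0 with the replicate block, 2 with features of no gene name kept, 15 without vector replicate 1, and 0 without vector replicate 2, vector replicate 3, knockout replicate 1 or knockout replicate 2. On simulated counts of these libraries, with 200 changed genes, the test called 80% of 2-fold and 34% of 1.5-fold changes. The Benjamini-Hochberg cutoff is stricter where fewer genes change, so these shares do not carry over to a result of 1 gene.

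In tumours of hosts given T cells, some liver-specific transcripts fell and some cell cycle transcripts rose with the knockout. Of 26 proliferation genes 6 rose and all 26 had positive fold changes (camera adjusted p = 3.85e-13; adjusted p = 0.407 with an estimated correlation). The 6 became 0 without vector replicate 1, vector replicate 3, knockout replicate 1, knockout replicate 2 or knockout replicate 3, and 22 without vector replicate 2. PLK1 went from 71.8 ± 5.83 to 104 ± 1.72 CPM (log2 fold change 0.54, SE 0.11, edgeR adjusted p = 0.0338). CCNB1 rose from 117 ± 13 to 175 ± 6.67 CPM, BUB1 from 54.5 ± 5.59 to 89.1 ± 13.9 and AURKA from 74.5 ± 8.01 to 112 ± 8.13. Of 20 hepatocyte proteins 7 fell (camera adjusted p = 3.01e-12; adjusted p = 0.326 with an estimated correlation). The 7 became 0 without vector replicate 1, knockout replicate 1 or knockout replicate 3, 2 without vector replicate 3, 3 without knockout replicate 2 and 16 without vector replicate 2. The plasma protein gene AHSG fell from 3860 ± 491 to 2120 ± 60.5 CPM (-0.86, SE 0.12, edgeR adjusted p = 0.0202). Transferrin (TF, 10700 ± 2110 to 5480 ± 646 CPM), ITIH1 (124 ± 45.6 to 45.3 ± 3.23) and haptoglobin (HP, 493 ± 317 to 112 ± 21) fell with it. CPT1A, which controls entry of fatty acids into mitochondria, fell from 160 ± 82.5 to 33.5 ± 1.07 CPM (-2.26, SE 0.33, edgeR adjusted p = 0.0202). Markers of T cells were lower as well, CD3G at -1.997 (edgeR adjusted p = 0.0202) and CD3D at -1.02 (0.0289), 2 of the 8 markers tested. In cultured Huh7, grown without T cells, the 2 markers tested, CD7 and IL2RG, were also lower past the threshold with the knockout (median -0.41). A fall of such markers therefore does not by itself show fewer T cells. In tumours of hosts given PBS, CD3G stood at 18.6 ± 10.3 CPM with vector and 7.97 ± 5.37 with knockout (-1.24, edgeR adjusted p = 0.918) and CD3D at 23.3 ± 5.4 and 14.8 ± 7.46 (-0.66, 0.925).

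The largest other rises in T cell tumours were in the ubiquitin hydrolase gene UCHL1 (46.3 ± 16.2 to 158 ± 43.7 CPM), OLFM2 (11.8 ± 1.09 to 33.0 ± 9.71), and CRISP3 (8.73 ± 1.8 to 23 ± 2.68). They were joined by THBS1, the matrix protein thrombospondin (23 ± 7.26 to 58.8 ± 22.3), the oncogene MYCN (36.9 ± 12 to 95.2 ± 26.8) and HS6ST2 (3.92 ± 0.7 to 9.84 ± 1.67). The largest falls were in the readthrough transcript CHURC1-FNTB (6.97 ± 1.26 CPM with vector; 0, 0 and 0.812 CPM in the knockout libraries) and LBP, which binds bacterial lipopolysaccharide in plasma (98.1 ± 84.9 to 7.15 ± 3.55 CPM). Next came HIF3A (11.8 ± 4.76 to 1.6 ± 1.16), FXYD1 (17.5 ± 11.5 to 2.62 ± 1.05), AQP10 (89.6 ± 61.9 to 15.6 ± 3.32) and the complement gene C4A (247 ± 132 to 44.7 ± 3.8). Reads of CHURC1-FNTB overlap its parent genes, and C4A has the near-identical copy C4B. Hypoxia and glycolysis genes held 5 lower of 20, among them PDK1 (126 ± 3.68 to 70.5 ± 2.26 CPM) and NDRG1 (618 ± 148 to 256 ± 28.1). P4HA1 (212 ± 67.6 to 102 ± 12.2) and PGK1 (366 ± 25.3 to 248 ± 19.5) were others. Fatty acid oxidation held 5 lower of 15, including the regulators PPARA (133 ± 23.9 to 70.9 ± 13.4 CPM) and PPARGC1A (log2 fold change -1.75). Bile acid genes held 4 lower of 13: the transporters SLC51A (100 ± 20.5 to 38.7 ± 7.27 CPM), ABCB11 (5.88 ± 2.45 to 1.45 ± 0.83) and ABCC3 (56.2 ± 24.1 to 20.9 ± 3.18) fell. BAAT fell from 16.8 ± 0.537 to 4.14 ± 2.77 CPM. In MHC class I presentation HLA-E and B2M fell by 0.93 and 0.54, 2 of 19 tested.

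In T cell tumours 500 of 13119 genes passed, 144 higher and 356 lower, and 226 changed at least 2-fold. By camera 10 of 26 lists passed: proliferation (adjusted p = 3.85e-13; adjusted p = 0.407 with an estimated correlation), hepatocyte proteins (3.01e-12; 0.326), hypoxia and glycolysis (4.8e-08; 0.326), fatty acid oxidation (3.72e-05; 0.352) and bile acid genes (4.63e-05; 0.326), the last value in each bracket being the adjusted p with an estimated correlation. The others were T cell markers (adjusted p = 0.000657; adjusted p = 0.326 with an estimated correlation), lipid droplet genes (0.00214; 0.326), type I interferon genes (0.0101; 0.683), MHC class I presentation (0.0116; 0.407) and mesenchymal genes (0.0356; 0.407). Of lipid droplet genes 2 of 20 were lower and of mesenchymal genes 1 of 13. Adjusted over the list alone, 18 proliferation genes were higher. Lower over the list alone were 17 hepatocyte proteins, 7 hypoxia, 6 fatty acid oxidation, 8 bile acid, 3 T cell marker, 7 lipid droplet, 5 MHC class I and 2 mesenchymal genes. None of the 22 interferon genes passed in edgeR, their median being -0.50. With the replicate number as a block, which treats these libraries as paired, 1217 genes passed (525 higher, 692 lower), including 493 of the 500. The same block also brought MHC class II genes (camera adjusted p = 0.115 without and 0.0253 with it) and checkpoint ligands (0.0652 and 0.0178) past the threshold (adjusted p = 0.409 with an estimated correlation for both). DESeq2 called 1747 genes, a fit of all 12 tumours 973 and a fit with unnamed features 207. Single libraries decided much of the count, which was 0 without vector replicate 1, 2083 without vector replicate 2, 105 without vector replicate 3, 0 without knockout replicate 1, 242 without the shallow knockout replicate 2 and 1 without knockout replicate 3.

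T cell against PBS tumours were compared to ask what the injected cells changed in tumours of either genotype. The PBS and T cell tumours come in separate tables, so treatment and table cannot be told apart in these comparisons. In vector tumours no gene of 12877 passed in edgeR, with the smallest adjusted p at 0.0527, 2714 genes at an unadjusted p under 0.05 and 966 called by DESeq2. PLK1 stood at 102 ± 6.04 CPM with PBS and 70.6 ± 5.59 with T cells (log2 fold change -0.53, SE 0.10, edgeR adjusted p = 0.0617), and CDC20 at 132 ± 17 and 86.8 ± 3.67 (-0.60, 0.0617). ATF4, the regulator of the amino acid response, stood at 523 ± 12.1 and 370 ± 23.6 CPM (-0.50, edgeR adjusted p = 0.0569). Interferon-induced genes had positive fold changes in 17 of 21 cases. MX1 stood at 14.7 ± 6.45 CPM with PBS and 33.8 ± 13.9 with T cells (1.19, edgeR adjusted p = 0.18). The antigen processing genes TAPBP and PSMB8 stood at 30.5 ± 6.22 and 63.7 ± 11.4 CPM (1.06, 0.0891) and at 3.4 ± 0.783 and 6.47 ± 0.86 CPM (0.92, 0.103). The 7 T cell markers tested had a median of 0.14 (camera adjusted p = 0.527).

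By camera 5 of 25 lists passed between vector tumours. Proliferation genes ranked lower (median -0.41, adjusted p = 1.31e-10, 17 lower when adjusted over the list alone; adjusted p = 0.635 with an estimated correlation). The ER stress list did so too (-0.24, 0.042, 1 lower when adjusted over the list alone; adjusted p = 0.635 with an estimated correlation). Ranked higher were type I interferon genes (median 0.56, adjusted p = 0.00719; adjusted p = 0.638 with an estimated correlation), LXR targets (0.35, 0.042) and MHC class I presentation (0.24, 0.0465). For the last pair adjusted p = 0.635 with an estimated correlation, and 2 MHC class I genes were higher when adjusted over the list alone. The count of 0 became 1 with the replicate block, 153 without T cell vector replicate 2, 30 without T cell knockout replicate 2 and 1 without PBS knockout replicate 2.

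In knockout tumours, FGF2, a fibroblast growth factor, was higher with T cells, at 11.4 ± 1.04 CPM against 3.85 ± 0.932 with PBS (log2 fold change 1.57, SE 0.27, edgeR adjusted p = 0.0333). MDFIC, a transcriptional regulator, went from 22.9 ± 1.28 to 52.4 ± 5.54 CPM (1.19, SE 0.12, edgeR adjusted p = 0.00248). LYPLA1, a depalmitoylating enzyme, rose from 41.6 ± 1.76 to 87.6 ± 12.3 CPM, NFIB from 2.82 ± 0.353 to 6.93 ± 1.54, ZBED6 from 47.0 ± 5.91 to 120 ± 33.4 and DYNLT5 from 4.0 ± 0.188 to 8.89 ± 1.45. The hypoxia-induced gene NDRG1 fell from 520 ± 57.5 to 253 ± 28.6 CPM (-1.04, SE 0.22, edgeR adjusted p = 0.0477). PMM1 (59.2 ± 3.94 to 34.5 ± 3.24 CPM), VGLL4 (42.9 ± 6.23 to 25.4 ± 3.54) and the ribonuclease gene ANG (51.5 ± 3.67 to 30.9 ± 3.75) fell too. ZNF600 fell from 22.9 ± 1.24 to 14 ± 1.1 CPM, and POLR2J3, which has near-identical copies, from 21.4 ± 4.85 to 12.5 ± 1.92. Hepatocyte proteins ranked lower as a set without a member past the threshold (camera adjusted p = 1.09e-06; adjusted p = 0.75 with an estimated correlation). SERPINA1 stood at 8070 ± 396 CPM with PBS and 5890 ± 551 with T cells (-0.45, edgeR adjusted p = 0.0565).

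Of 12877 genes 138 passed between knockout tumours, 120 higher and 18 lower, and 13 changed at least 2-fold. By camera 3 of 25 lists passed, all lower: hepatocyte proteins (median -0.36, adjusted p = 1.09e-06, 9 lower when adjusted over the list alone), hypoxia and glycolysis (-0.33, 0.00226, 1 of 20 lower and 1 alone) and fatty acid oxidation (-0.40, 0.01, 4 alone). Each had adjusted p = 0.75 with an estimated correlation. DESeq2 called 1108 genes and the replicate block 316 (247 higher, 69 lower). With the block the immediate early genes passed camera (adjusted p = 0.0419 with and 0.0867 without the block; adjusted p = 0.768 with an estimated correlation). Leaving out 1 library gave 294, 10 and 14 genes for PBS vector replicates 1, 2 and 3, and 1 for each PBS knockout replicate. It gave 9, 351 and 151 for T cell vector replicates 1, 2 and 3, and 18, 23 and 1 for T cell knockout replicates 1, 2 and 3.

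Whether the knockout acts otherwise in the presence of T cells was tested as an interaction over the 12 tumours. Proliferation genes had positive differences throughout, 26 of 26, with a median of 0.51 (camera adjusted p = 7.7e-13; adjusted p = 0.46 with an estimated correlation). Hepatocyte proteins had negative ones in 19 of 20 cases, with a median of -0.61 (5.75e-11; adjusted p = 0.46 with an estimated correlation). PLK1 stood at 102 ± 6.04 and 95.1 ± 9.89 CPM in vector and knockout PBS tumours and at 70.6 ± 5.59 and 103 ± 2.79 CPM in T cell tumours, a difference of 0.65 (SE 0.14, edgeR adjusted p = 0.374). CPT1A stood at 86.0 ± 43.4, 107 ± 44.3, 158 ± 80.9 and 33.2 ± 1.46 CPM in the same order, a difference of -2.56 (SE 0.61, edgeR adjusted p = 0.374). No gene of 12877 passed in edgeR, with 1574 at an unadjusted p under 0.05, and DESeq2 called 13 (6 higher, 7 lower). On simulated counts with 200 changed genes the test called 38% of 2-fold differences. With fewer changed genes this share would be lower.

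Of the 25 lists tested for this interaction 9 passed camera. Besides those 2, type I interferon genes (median -0.66, adjusted p = 0.000215), fatty acid oxidation (-0.50, 0.000215), and LXR targets (-0.35, 0.00588) ranked lower, at adjusted p = 0.466, 0.46 and 0.46 with an estimated correlation. So did lipid droplet genes (-0.29, 0.0148), bile acid genes (-0.58, 0.0156), MHC class I presentation (-0.24, 0.0156) and hypoxia and glycolysis (-0.23, 0.0156). With an estimated correlation these 4 had adjusted p = 0.466, 0.46, 0.466 and 0.564. Adjusted over the list alone, 9 proliferation genes were higher, and 12 hepatocyte proteins and 3 fatty acid oxidation genes lower. As the mean log2 CPM of a list, the knockout effect on proliferation differed by 0.52 (95% interval -0.03 to 1.06) and that on hepatocyte proteins by -0.69 (-1.23 to -0.14). Exact permutation p-values were 0.105 and 0.065, both 0.165 after adjustment over 6 lists.

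**Figure D3:**
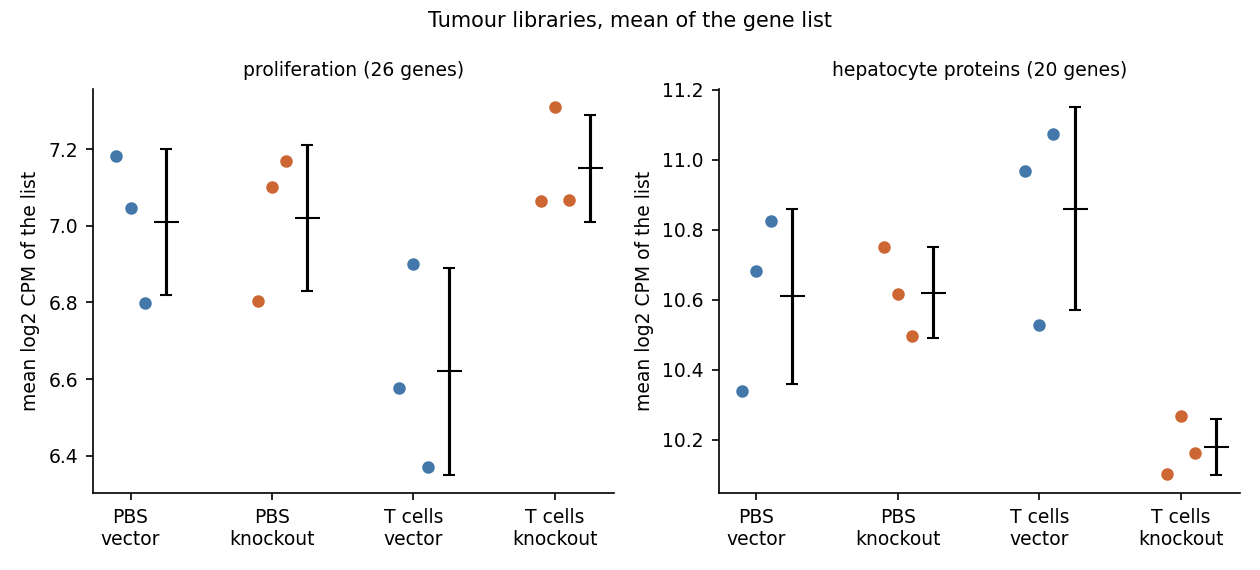
Mean log2 CPM of the 26 proliferation genes and of the 20 hepatocyte proteins in each of the 12 tumour libraries; points are libraries, and the bar beside them the mean and SD of the group. Proliferation genes average 6.62 ± 0.27 in vector and 7.15 ± 0.14 in knockout T cell tumours, and hepatocyte proteins 10.86 ± 0.29 and 10.18 ± 0.08.

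Growth as a tumour was set against culture to ask whether the knockout moves the same Huh7 genes in both settings, using reads rebuilt for the culture libraries. The fall of cholesterol synthesis genes in culture was smaller in PBS tumours: the difference was positive for 25 of 25 genes and passed for 14 (camera adjusted p = 9.34e-12; adjusted p = 0.213 with an estimated correlation). MSMO1 went from 366 ± 37.1 to 205 ± 11 CPM in culture and stood at 250 ± 20.3 and 232 ± 12.2 CPM in tumours (difference 0.73, SE 0.12, edgeR adjusted p = 0.00547). FDFT1, MVK and FDPS had differences of 0.78, 0.60 and 0.52. FGB went from 832 ± 7.45 to 2070 ± 22.8 CPM in culture and stood at 1290 ± 92.4 and 1340 ± 178 CPM in tumours (-1.26, SE 0.12, edgeR adjusted p = 0.000169). The glycolytic gene ENO1 went from 941 ± 17.7 to 1450 ± 15.2 CPM in culture and stood at 2020 ± 227 and 1720 ± 285 CPM in tumours (-0.86, SE 0.15, edgeR adjusted p = 0.00649). SOAT1 did not differ past the threshold (0.10, SE 0.15, edgeR adjusted p = 0.699).

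Other genes with a knockout effect that was lower in tumours than in culture included LDHA and HK2 (-0.78 and -1.05), the hepatocyte proteins FGG, AFP and HP (-0.90, -0.48 and -2.05) and the NRF2 targets SRXN1, TFRC, FTL and GCLM (-0.45, -0.61, -0.37 and -0.74). COL6A1 and TAGLN of the matrix list (0.46 and 1.23) and P4HA2 of the hypoxia list (0.61) lay higher. The largest differences included LCN2, at 4.46 ± 0.428 and 20.7 ± 1.27 CPM in culture and 1.72 ± 1.2 and 0.685 ± 0.31 in tumours (-3.56, SE 0.54, edgeR adjusted p = 0.00368). YPEL1 stood at 5.67 ± 0.548 and 1.12 ± 0.0909 CPM in culture and 1.39 ± 0.355 and 1.62 ± 0.354 in tumours (2.51, SE 0.34, edgeR adjusted p = 0.00176). LAMP5, LOXL4 and LEFTY1 differed by 3.05, 2.88 and 2.39, and IRAK3 and U2AF1, the last of which has a duplicate copy, by -2.59 and -2.95. For TBC1D3I (5.98), BBOX1 (2.88), TUBB1 (-3.74), RNF183 (-3.65) and AS3MT (-2.91), a culture group lay under the level of 3 reads, 0.077 to 0.094 CPM, so the fitted size is no bound.

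In all, 1274 of 12623 shared genes passed this interaction, 629 higher and 645 lower. By camera 5 of 24 lists passed: cholesterol synthesis (adjusted p = 9.34e-12; adjusted p = 0.213 with an estimated correlation), hypoxia and glycolysis (4.13e-05; 0.53), hepatocyte proteins (7.8e-05; 0.451), NRF2 targets (0.00761; 0.213) and fibroblast and matrix genes (0.0453; 0.213), the last value in each bracket being the adjusted p with an estimated correlation. Of hypoxia genes 1 of 20 was higher and 4 lower, of hepatocyte proteins 6 of 20 lower, of NRF2 targets 4 of 16 lower and of matrix genes 2 of 10 higher. Adjusted over the list alone the members were 18 higher, 1 higher and 10 lower, 7 lower, 1 higher and 6 lower, and 4 higher, in that order. Growth setting and table cannot be told apart, since culture and tumour values came from separate tables. The count was 571, 516 and 668 without culture vector replicates 1, 2 and 3, 567, 490 and 504 without culture knockout replicates 1, 2 and 3, and 1971 without PBS vector replicate 1.

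**Figure D4:**
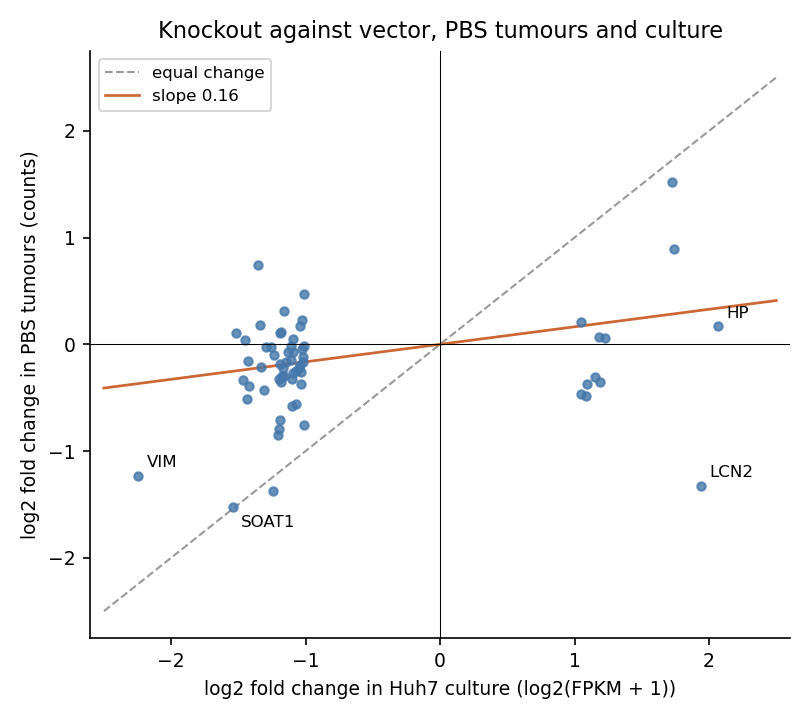
Log2 fold change of knockout against vector in PBS tumours (vertical axis, counts) against that in cultured Huh7 (horizontal axis, log2(FPKM + 1)) for the 63 genes past the threshold and at least 2-fold in culture. The slope fitted through the origin is 0.16, against 1 for the dashed line of equal change, and 46 of the 63 genes have the same sign in both. Of all 73 such genes in culture, 59 were lower, so a shared mean fall enters both values.

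The gene sets of the 4 knockout comparisons were then compared by Fisher's exact test, 12 tests in all. These tests take genes as independent units, which they are not, so their p-values do not measure the spread between libraries. Genes higher in cultured Huh7 were also higher in T cell tumours for 81 genes where independent lists would give 29.5 (odds ratio 5.29, adjusted p = 1.75e-20). Another 132 were lower in both against 85.5 (2.23, 5.35e-09), while 43 were higher in culture and lower in T cell tumours and 9 the other way. Across genes, which are not independent replicates, the fold changes of these experiments had r = 0.31 and rho = 0.38. For the 64 genes past the threshold and at least 2-fold in culture r was -0.04, and 45 had the same sign in both. The slope of their T cell tumour on culture values, fitted through the origin, was 0.185 (95% interval 0.095 to 0.275). Of the 73 genes at least 2-fold changed in culture, 59 were lower. A shared mean fall alone can therefore give such a slope and such a count of signs. Between Hepa1-6 and cultured Huh7, 181 genes were lower in both against 143 from independent lists (odds ratio 1.48, adjusted p = 0.000496). There were 117 higher in both against 128 (0.889, adjusted p = 0.509), and r was -0.01. Genes higher in Hepa1-6 and lower in Huh7 numbered 236, and 91 went the other way (210 and 232 with edgeR on rebuilt reads). Of 8208 genes tested in both lines, 2713 were lower in Huh7. They included 236 of the 569 genes higher in Hepa1-6 and 181 of the 434 lower there. The excess of genes lower in Huh7 was therefore not particular to genes lower in Hepa1-6. With edgeR on rebuilt reads the shared fall of the cultured lines no longer passed (odds ratio 1.22, adjusted p = 0.0624). The shared higher genes then passed as fewer than independent lists give, 168 against 196 (odds ratio 0.791, adjusted p = 0.0484). Hepa1-6 and T cell tumours shared 9 higher and 12 lower genes, against 8.69 and 7.95 (adjusted p = 1 and 0.278). Without a filter on low values the 13 shared lower genes passed (adjusted p = 0.00915). The PBS tumours, with SOAT1 as their 1 call, had r = 0.19 with culture and r = 0.31 with T cell tumours.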

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

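The test of depth was written after the result was seen, and the comparison of culture with PBS tumours on rebuilt reads was added after the unit of the culture tables was known. Cultured Huh7 had 6322 genes past the threshold and PBS tumours 1. The PBS fold changes of the 63 genes that changed at least 2-fold in culture had a slope through the origin of 0.164 on the culture values (95% interval 0.014 to 0.314). Without SOAT1 it was 0.144 (-0.008 to 0.296). Both lay under the bound of 0.8 that wider spread alone would give. Lower depth would widen the spread without shrinking fold changes, so the same slope argues against it as the whole cause. The ratio of median totals, 1.13 for PBS tumours over culture, does not decide by itself, since PBS totals ran from 29.9 to 114.2 M and culture totals from 31.8 to 38.8 M. A knockout effect that differs between settings may explain the pattern, with 1274 genes past the threshold of the interaction, but setting and table are the same variable here.

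Genes with the largest such differences (log2, PBS tumours minus culture) were TBC1D3I at 5.978, LAMP5 at 3.053, LOXL4 at 2.884, BBOX1 at 2.883, YPEL1 at 2.511 and LEFTY1 at 2.394, and TUBB1 at -3.743, RNF183 at -3.649, LCN2 at -3.559, U2AF1 at -2.947, AS3MT at -2.907 and IRAK3 at -2.594. TBC1D3I, BBOX1, TUBB1, RNF183 and AS3MT had a culture group under the level of 3 reads, and TBC1D3I and U2AF1 have near-identical copies. List medians of the same difference were 0.461 for cholesterol synthesis and uptake, -0.655 for hypoxia and glycolysis, -0.244 for hepatocyte proteins, -0.274 for NRF2 targets and ferroptosis and 0.364 for fibroblast and matrix genes. None of these lists passed camera with an estimated correlation. Of 50 splits drawn from 200, 6 gave as many genes as the real 1274, itself among them, and the highest had 3294. The other 5 kept the culture groups whole, and with them the knockout effect in culture, while the 38 splits mixed in both tables gave 0. This count therefore neither excludes chance nor points to it.

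Hepatocyte proteins were lower and proliferation genes higher in knockout than in vector T cell tumours. The shallow knockout replicate 2 does not account for it, since the smaller list median kept 85.5% of its size without that library, and over all 6 leave-one-out fits the smallest kept 81.2%. Calls of single genes did depend on it: proliferation genes past the threshold went from 6 to 0 and hepatocyte proteins from 7 to 3 without that library. Whether the effect depends on T cells could not be told: the differences from PBS tumours were 0.516 for proliferation (95% interval -0.028 to 1.059, exact permutation p = 0.105) and -0.686 for hepatocyte proteins (-1.233 to -0.138, p = 0.065), over 400 assignments, with both at 0.165 after adjustment over 6 lists. The interval and the permutation leave out the pairing of the T cell tumours by number, which was inferred from the data. For both lists every knockout T cell tumour lay beyond every vector one. Any pairing of these libraries therefore gives the same direction in 3 of 3 pairs, which adds no support. Within T cell tumours alone the exact p was 0.1, the smallest that 3 against 3 can give.

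Medians of the knockout effect in T cell minus PBS tumours were 0.506 for proliferation, -0.609 for hepatocyte proteins, -0.503 for fatty acid oxidation and PPARA targets, -0.655 for type I interferon genes, -0.352 for LXR targets and cholesterol efflux, -0.288 for lipid droplet genes, -0.241 for MHC class I presentation, -0.235 for hypoxia and glycolysis and -0.585 for bile acid genes. None of the 9 passed camera with an estimated correlation, and edgeR called 0 genes (1574 at an unadjusted p under 0.05, DESeq2 13). All 50 of 50 drawn splits reach the real count of 0 by construction, so they say nothing of chance. The highest had 1987 and kept the T cell groups whole, with the PBS groups mixed.

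T cell markers did not pass as higher in T cell than in PBS tumours with vector (median 0.135, camera adjusted p = 0.527), although several means lay higher. Over both genotypes CD3D averaged 22.7 and 21.7 FPKM, CD7 70.5 and 65.6, CD3G 6.69 and 4.03 and CD4 0.426 and 0.296. With vector alone CD3D averaged 30 and 26 FPKM, CD7 81.7 and 60.5, CD3G 10.7 and 5.59 and CD4 0.528 and 0.269, whereas CD8B averaged 1.97 and 2.74, CD27 0.924 and 1.07 and LAT 1.48 and 1.76. With knockout alone CD3D averaged 15.3 and 17.3 FPKM, CD7 59.3 and 70.7, CD27 0.668 and 0.817 and LAT 1.74 and 2.13. There CD3G averaged 2.71 and 2.48, CD4 0.325 and 0.322 and CD8B 2.05 and 1.62. Huh7 grown in culture held CD7 at 15.7 FPKM, a ratio of 0.223 to T cell tumours, which neither excludes nor establishes Huh7 cells as a candidate source, and CD3D at 0.617 FPKM. PBS tumours held CD3D, CD7, CD3G and CD4 at 0.956, 0.931, 0.603 and 0.693 of their level in T cell tumours. For CD8B, CD27 and LAT the ratios were 1.09, 1.19 and 1.21. Hosts of PBS tumours were given no T cells, so these ratios argue against injected T cells as the source of most reads of these genes. The T cell tumour table lists 8 of the 24 fixed markers, so markers missing from the listed genes may hide a difference.

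With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real count and the highest of the other splits were 1329 and 0 in Hepa1-6, 6322 and 0 in cultured Huh7, 1 and 4 in PBS tumours (5 splits as large, the real one included), 500 and 0 in T cell tumours, 0 and 0 between vector tumours (10 of 10 as large) and 138 and 0 between knockout tumours. In T cell tumours, whose libraries were taken as paired by number, the other splits that part all 3 pairs also gave 0. The real split alone, 1 of 10, was as large in Hepa1-6, cultured Huh7, T cell tumours and knockout tumours.

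Of 41 named genes with values in both cultured lines, 30 had groups apart in both, 24 in the same direction and 6 in opposite ones, a difference that was not tested. The opposite ones were Tgfbi at 1.202 in Hepa1-6 and TGFBI at -0.293 in Huh7, Edn1 at -1.043 and EDN1 at 0.136, Itih2 at 0.543 and ITIH2 at -0.127, Apoe at 0.537 and APOE at -0.185, Klhl24 at 0.317 and KLHL24 at -1.453, and Srxn1 at -0.194 and SRXN1 at 0.469. Of these, EDN1 did not pass in Huh7 (adjusted p = 0.0613), nor Klhl24 and Srxn1 in Hepa1-6 (0.0527 and 0.0885). The named genes were chosen for passing in a line. Among all genes past the threshold in both lines 117 were higher and 181 lower in both, 236 higher in Hepa1-6 and lower in Huh7, and 91 the other way. With edgeR on rebuilt reads the last pair of counts was 210 and 232. Groups of 3 against 3 fall apart by chance in 10% of genes.

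Among features without a gene name, edgeR called 1 in PBS tumours and 11 in T cell tumours. MSTRG.6869.26 had 0 counts in each PBS vector library and 97 to 185 in the knockout libraries, at least 280-fold higher against a floor of 3 counts over the group (adjusted p = 0.0382). In T cell tumours 6 features were at 0 in each knockout library, among them MSTRG.14461.24 with 106 to 386 counts with vector (at least 133-fold lower, adjusted p = 0.0315) and MSTRG.27840.8 with 124 to 286 (at least 122-fold lower, adjusted p = 0.0256).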

How the results depend on the processing

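Counts of genes past the threshold are given for the settings that moved them by more than 1.5 times, with a few that did not, and the cause was not tested. Planned count-based settings for cultured cells were not run as written because those tables hold FPKM. Hepa1-6 gave 1329 genes, 712 with no filter on low values, and 572, 572 and 2027 without vector replicates 1, 2 and 3 and 409, 357 and 1081 without knockout replicates 1, 2 and 3. PBS tumours gave 1 gene in edgeR (682 at an unadjusted p under 0.05), 61 in DESeq2, 0 with the replicate block, 2 with unnamed features (added), 15, 0 and 0 without vector replicates 1, 2 and 3 and 0, 0 and 1 without knockout replicates 1, 2 and 3. T cell tumours gave 500, 1747 in DESeq2, 1217 with the replicate block, 973 in the fit of 12 tumours, 207 with unnamed features (added; 196 shared with the 500), 0, 2083 and 105 without vector replicates 1, 2 and 3 and 0, 242 and 1 without knockout replicates 1, 2 and 3. Vector tumours gave 0 in edgeR (2714 at an unadjusted p under 0.05), 966 in DESeq2, 1 with the replicate block, and 153, 30 and 1 without T cell vector replicate 2, T cell knockout replicate 2 and PBS knockout replicate 2. Knockout tumours gave 138, 1108 in DESeq2, 316 with the replicate block, 294, 10 and 14 without PBS vector replicates 1, 2 and 3, 1 without each PBS knockout replicate, 9, 351 and 151 without T cell vector replicates 1, 2 and 3 and 18, 23 and 1 without T cell knockout replicates 1, 2 and 3. The interaction with T cells gave 0 in edgeR (1574 at an unadjusted p under 0.05), 13 in DESeq2, 0 with the replicate block and 0 without any single library. The interaction with growth (added) gave 1274, 571, 516 and 668 without culture vector replicates 1, 2 and 3, 567, 490 and 504 without culture knockout replicates 1, 2 and 3, 1971 without PBS vector replicate 1 and 973 with the replicate block. Count tests on rebuilt reads (added) gave 1658 (784 higher, 874 lower) in edgeR with TMM, 1657 (775, 882) with RLE and 1925 (906, 1019) in DESeq2 for Hepa1-6, and 7615 (3842, 3773), 7637 (3897, 3740) and 7130 (3776, 3354) for cultured Huh7.

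Over the 8 comparisons 56 list tests passed camera, 0 with an estimated correlation, 25 with fry and 58 with the replicate block. For knockout against vector no list passed fry in PBS or T cell tumours, with smallest fry adjusted p of 0.612 and 0.0739. Fry also passed lists that camera did not, such as interferon gamma genes in cultured Huh7 (fry adjusted p = 0.000426, camera adjusted p = 0.285). Under the block the interferon list of PBS tumours was lost (adjusted p = 0.078), MHC class II genes and checkpoint ligands in T cell tumours (0.0253 and 0.0178) and immediate early genes between knockout tumours (0.0419) were gained, and no other list call changed. Of the 12 overlap tests 3 passed with more shared genes than independent lists give, 3 with RLE, 4 with no filter, 3 with the stricter filter, 2 with a 2-fold threshold and 2 on rebuilt reads, where 1 more passed with fewer shared genes (odds ratio 0.791). The cultured lines kept their main fits under RLE and the stricter filter. The stricter filter therefore changed no overlap and tested nothing, and RLE altered the tumour fits alone. With no filter and with the 2-fold threshold, the cultured lines shared 56 and 0 higher genes (117 as reported) and 107 and 0 lower ones (181), and Hepa1-6 and T cell tumours 3 and 0 higher (9) and 13 and 1 lower (12). Cultured Huh7 and T cell tumours shared 0 higher genes (81) and 8 lower ones (132) with the 2-fold threshold. Replicate numbers did not meet the rule for pairs, each same-number correlation over 0.1, in the other comparisons checked: same-number correlations were 0.04 to 0.1 in Hepa1-6, where each library lay closest to its own number, a hint from the data, 0 to 0.17 in cultured Huh7 and -0.08 to 0.05 in PBS tumours. Between PBS and T cell tumours they were -0.17 to 0.39 with vector and -0.13 to 0.08 with knockout. The block gave 1184 genes in Hepa1-6 and 6427 in cultured Huh7. Named genes made 207 entries, as a gene counts once in each comparison that names it. Of their 3182 values 2768 had the same result, passed or not, 378 lost a call (342 of them on leaving out a library), 35 gained one and 1 was reversed. Calls were lost for 151 of 429 values in T cell tumours, 94 of 357 between knockout tumours, 96 of 527 for the interaction with growth, 32 of 447 in Hepa1-6 and 0 of 435 in cultured Huh7. The reversed value was the SOAT1 interaction with growth at -0.05 without PBS knockout replicate 3 (edgeR adjusted p = 0.812), against 0.10 with all libraries and 0.178 without PBS knockout replicate 1.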

Other observations

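The genes in these observations were picked after their values were seen. In cultured Huh7 the ER stress list did not pass as a whole (camera adjusted p = 0.861) and its members went both ways, 6 of 19 higher and 10 lower. The chaperone gene HSPA5 rose from 201.8 ± 5.22 to 364.5 ± 2.57 FPKM (limma adjusted p = 4.85e-08), and XBP1, DNAJB9 and HERPUD1 rose by 0.57, 0.63 and 0.43. Among the lower members PHGDH, of serine synthesis, fell from 36.67 ± 1.23 to 17.55 ± 0.329 FPKM, TRIB3 by 0.70, CHAC1 by 0.69 and DDIT3 by 0.46. In the interaction with growth HSPA5 and XBP1 differed by -1.22 and -0.96 (edgeR adjusted p = 0.00945 and 0.000121). The heat shock genes HSPA1A and HSPA1B, whose sequences are nearly the same, rose by 1.09 and 1.05 in culture.

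Genes of MHC class I presentation were split in cultured Huh7 as well, 7 of 16 higher and 5 lower (camera adjusted p = 0.439). HLA-E fell from 10.01 ± 0.255 to 5.649 ± 0.596 FPKM and B2M from 103.9 ± 2.83 to 81.96 ± 0.91, while the chaperone CANX rose from 152.4 ± 6.26 to 233.0 ± 1.68 FPKM. In Hepa1-6 the hepatocyte transcription factors Prox1, Foxa3 and Onecut1 rose by 0.55, 0.49 and 0.52, and Trib3 rose by 0.54 (limma adjusted p = 0.0102).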
